A study of Mus musculus with 128 samples.

How the data were processed

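Liver RNA of male mice was sequenced in libraries that form 26 groups of strain, drink and time. Per the labels' protocols, mice were killed at each time and their livers taken. That each replicate is a separate mouse is read from this and not stated outright, and the p-values measure the spread between these libraries. Libraries were made with the NEBNext kit and sequenced on a NovaSeq 6000 as 150 bp paired reads, per the labels' protocols.

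The values used are read counts per gene as the authors deposited them, without normalization. Reads were processed with CASAVA, STAR 2.5, HTSeq 0.6.1 and DESeq2 against mm10 (GRCm38), per the submitters' processing notes, which give no role or order for these tools. Whether counting used the strand of the reads is not given in the sources used here, so overlapping and antisense genes, and near-identical families such as the Mup, Saa and Acsm genes, carry uncertain counts. FPKM values that the authors deposited for the same libraries were not used. The count table held 35275 genes, of which 8695 had no read in any library, and 0 columns of per-sample values were left unused. Of 34490 gene identifiers also found in the GENCODE M21 annotation of GRCm38, 34447 (99.88%) overlapped the annotated gene on the same chromosome and 24932 had identical ends. Coordinates are those of the deposited table.

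Total counts were 18541545 to 43118895 per library. Mitochondrially encoded genes took 3.03% to 14.13% of counts, and the 20 most abundant genes 18.65% to 31.62%. No pair of libraries within a group agreed within sampling noise: 0 libraries were identical, and the lowest chi-square per degree of freedom was 19.17. The names of 34 libraries end in an appended letter a, and its meaning is not given in the sources used here. The suffix accounted for 38.6% of the first principal component of the residuals, which held 13.5% of the residual variance. The suffix was treated as a technical batch. It marks no library of replicates 1 and 3, 20 of replicate 2, 2 of replicate 4 and 12 of replicate 5. Libraries with it were not tested alone, and within-batch values are given for the 94 libraries without it. On a scale of 200 genes with 0 at the C57BL6/J mean and 1 at the BALB/c mean, C57BL6/J libraries lay between -0.04 and 0.10 and BALB/c libraries between 0.94 and 1.03.

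Genes were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr over the 26 groups, which left 16886 genes, and library sizes were scaled by TMM. One model with a mean for each group was fitted to all libraries, so that all groups shared the estimate of spread. Contrasts were tested with the quasi-likelihood test with robust dispersions and Benjamini-Hochberg adjustment within each contrast, at an adjusted p of 0.05. The comparisons were water at 3, 6 and 12 h against 0 h, each sugar against water at the same time, each pair of sugars at the same time, and BALB/c against C57BL6/J at 0 h, with the mean of the strain effects taken in all but the last. Strain was also tested as an interaction with feeding time on water and with drink at each time. A log2 fold change is given with its standard error (SE) and, where an interval is given, at the 95% level. The count of libraries that show a direction sets each library against the mean CPM of the control group of its own strain. CPM used TMM-scaled library sizes, and log2 CPM a prior count of 1.

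Before the data were examined, 38 gene lists were fixed that cover metabolic pathways, stress responses, hepatocyte zones and other cell types. They held 590 symbols, of which 589 matched a gene, and 578 entries were tested. Each list was tested in 16 contrasts with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted within each contrast. The same test with an estimated correlation and fry were run beside it. Members called are counted with adjustment over all genes and adjusted over the list alone.

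Named genes followed a rule fixed before the data were examined. It takes a panel of 19 genes of fed and fasted metabolism, the clock and strain; per contrast up to 3 genes with the highest and 3 with the lowest log2 fold change among called genes with a mean CPM of at least 5, a gene symbol that is not a clone name, and the same sign in both strains; per called list up to 4 members with the smallest p; and per interaction test the 5 genes with the smallest p and a mean CPM of at least 5. Some genes chosen by this rule are not reported here. Transcripts of skeletal muscle, adrenal gland, kidney and stomach were summed per library after the data were examined, with 50 CPM as the level counted as present.

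Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, no filter on low counts, the replicate number as a block, the name suffix as a covariate, a model of the libraries of the contrast alone, and leaving out each replicate number in turn from all groups. Added after the data were examined were the libraries without the suffix, a model without 5 libraries whose profile lay nearer to another feeding time (by correlation over 300 genes per feeding contrast), and a model without BALB/c water 0 h replicate 1. For counts of called genes, 100 random splits of the same libraries were drawn.

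The tests were run on simulated counts made from real means and library sizes. For fructose against water at 3 h, 100 genes were changed 1.5-fold and 100 2-fold among 16587. In this test edgeR recovered 54% and 84% of them with 5 false calls among 143, and DESeq2 58% and 86% with 14 among 158. There camera called a list of 20 genes raised by design and not 20 unchanged genes. Since this follows from the design, it does not test the preset correlation. For strain by drink at 3 h, a simulation of 16587 genes with no interaction gave 0 calls.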

Results

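Nutrient regulation of liver gene expression was studied in male mice of the inbred strains C57BL6/J and BALB/c at 8 weeks of age. The mice were trained for 1 week to eat within a fixed evening window, fasted for 21 h and then offered chow at 7 pm, with fat supplying 10% and carbohydrate 64.5% of its calories. The drink was water, or water with 20% glucose, sucrose or fructose, and drinking water had been withheld from 4 pm. Glucose and fructose are monosaccharides, and sucrose is the disaccharide of both. Livers were taken at 0 h, before food was offered, and 3, 6 and 12 h after feeding began, so that each later time also differed from 0 h in time of day. Liver RNA was read as counts per gene, in 5 libraries in each of 24 groups and 4 in each of 2 groups (BALB/c with glucose and with fructose at 12 h). The total count per library was 18541545 to 43118895. Nnt, in which C57BL6/J carries a known deletion, gave 51.7 ± 3.38 CPM (SD, n = 5) in C57BL6/J and 131 ± 54.0 CPM in BALB/c at 0 h. Its log2 fold change was 1.34 ± 0.18 (SE, edgeR adjusted p = 8e-10, higher in 5 of 5 BALB/c libraries).

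In mice that drank water, genes of glucose production were lower at 3 h than at 0 h and genes of protein folding higher. Of fat and sterol synthesis, 7 of 20 and 15 of 25 genes rose, though as lists these were not called with an estimated correlation (camera adjusted p = 0.911 and 0.495). Pck1, the rate-limiting enzyme of gluconeogenesis (ENSMUSG00000027513, chromosome 2, 173153048 to 173159273, mm10), fell from 3330 ± 1879 CPM (SD, n = 5) to 274 ± 153 CPM in C57BL6/J and from 4038 ± 1296 to 478 ± 170.2 CPM in BALB/c. Its log2 fold change was -3.34 ± 0.49 (SE, edgeR adjusted p = 3.24e-08, lower in 10 of 10 libraries). C57BL6/J values at 0 h include replicate 2, with a fed profile and Pck1 at 160 CPM (others 3490 to 5150). G6pc, which releases free glucose, fell by 1.49 on the log2 scale (SE 0.29, edgeR adjusted p = 3.01e-05, 10 of 10). Fasn, the fatty acid synthase (ENSMUSG00000025153, chromosome 11, 120805940 to 120824178), rose from 256 ± 203 to 780.4 ± 130 CPM in C57BL6/J and from 67.2 ± 13.1 to 416 ± 132 CPM in BALB/c. Its log2 fold change was 2.12 ± 0.32 (edgeR adjusted p = 6.75e-08, 10 of 10). Srebf1, a transcriptional regulator of lipid synthesis, rose by 1.37 ± 0.19 (edgeR adjusted p = 6.64e-09, higher in 10 of 10). Txnip fell by 1.81 ± 0.28 (edgeR adjusted p = 1.38e-07), and Rgs16, a regulator of G protein signalling, by 5.67 ± 0.67 (3.52e-11), each in 10 of 10 libraries. Khk at 0.03, Pklr at 0.22, Cyp7a1 at -0.18 and Fgf21 at -1.38 ± 0.54 (edgeR adjusted p = 0.05) were not called.

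Among the largest rises at 3 h were those of Sdf2l1, a chaperone component of the endoplasmic reticulum (log2 fold change 2.67 ± 0.27, edgeR adjusted p = 9.65e-14, higher in 9 of 10 libraries), and Mvd of the mevalonate pathway (2.55 ± 0.29, 1.11e-11, 10 of 10). The largest falls were in Igfbp1, an insulin-repressed secreted protein (-7.46 ± 0.96, edgeR adjusted p = 5.69e-10), Ppp1r3g, a glycogen-targeting phosphatase subunit (-6.45 ± 0.70, 1.53e-12), and Rgs16, each lower in 10 of 10 libraries. Igfbp1 stood at 10550 CPM in BALB/c water 0 h replicate 1 and at 46 to 99.5 CPM in the other libraries of that group, and without replicate 1 the falls were -5.01 for Igfbp1 and -4.84 for Ppp1r3g.

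By list, 18 of 20 measured genes of the unfolded protein response rose at 3 h (19 rose and 1 fell adjusted over the list alone), among them Manf (2.06 ± 0.23) and Hyou1 (2.12 ± 0.24). The list had camera adjusted p = 1.03e-22, and 0.032 with an estimated correlation. Of 13 heat shock and cold-inducible genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone). Hsp90aa1 rose by 1.82 ± 0.20 and the cold-inducible Cirbp fell by 1.30 on the log2 scale. For the heat shock list camera gave adjusted p = 2.07e-08, and 0.032 with an estimated correlation. Of 16 genes of gluconeogenesis and FoxO1 targets, 12 fell (12 adjusted over the list alone), among them Foxo1 (-1.29 ± 0.14) and Ppargc1a (-2.18 ± 0.26). The list had camera adjusted p = 6.37e-08, and 0.0446 with an estimated correlation. Of 25 genes of cholesterol synthesis, 15 rose and 0 fell (15 adjusted over the list alone), with Insig1 at 1.44 ± 0.22. The list had a camera adjusted p of 1.87e-08, and 0.495 with an estimated correlation. Of 24 genes of ribosome biogenesis, 14 rose and 1 fell (16 and 2 adjusted over the list alone, Nop2 0.87 ± 0.12). As a set they had a camera adjusted p of 2.07e-08, and 0.357 with an estimated correlation. Of 20 lipogenesis genes, 7 rose and 2 fell (9 and 2 adjusted over the list alone), with Mid1ip1 at 1.84 ± 0.22 and Lpin1, a phosphatidate phosphatase that is also a fasting-induced coactivator, at -3.98 ± 0.44. Tested with camera, the list had adjusted p = 0.00579, and 0.911 with an estimated correlation. Of 21 genes of amino acid catabolism, 9 fell (9 adjusted over the list alone). By camera the list gave adjusted p = 0.0359 (0.335 without replicate 1, 0.0986 without replicate 4), and 0.911 with an estimated correlation.

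In all, edgeR called 4290 of 16886 genes at 3 h, 2148 higher and 2142 lower, of which 964 changed at least 2-fold. The count was 3943 in the libraries without the name suffix and 5107 without the 5 libraries that lay nearer to another feeding time.

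At 6 h on water the sterol list stood highest: 24 of 25 genes of cholesterol synthesis rose and 0 fell (24 adjusted over the list alone), with a median log2 fold change of 1.48. Mvd rose by 3.25 ± 0.30 (SE, edgeR adjusted p = 4.3e-16), Hmgcs1 by 2.56 ± 0.27 (9.73e-14) and Fdps by 2.38 ± 0.25 (1.14e-13), each higher in 10 of 10 libraries. The camera adjusted p was 1.2e-22, and 0.074 with an estimated correlation. In the unfolded protein response list 17 of 20 rose (18 adjusted over the list alone, Calr 1.61 ± 0.13). For this list camera gave adjusted p = 1.2e-22, and 0.0697 with an estimated correlation. Of 20 lipogenesis genes, 12 rose and 1 fell (12 and 2 adjusted over the list alone), with Fasn at 2.37 ± 0.32 and the ATP citrate lyase Acly at 1.96 ± 0.29. The list had a camera adjusted p of 4.82e-06, and 0.32 with an estimated correlation. Of 16 genes of gluconeogenesis and FoxO1 targets, 12 fell and 1 rose (13 and 1 adjusted over the list alone). As a set they had a camera adjusted p of 2e-05, and 0.12 with an estimated correlation. Pck1 was at -2.23 ± 0.47 (edgeR adjusted p = 7.26e-05, lower in 10 of 10 libraries), while G6pc at -0.63 (0.0909) was not called. The pentose phosphate list had 6 of 8 genes higher (6 higher and 1 lower adjusted over the list alone, Pgd 1.10 ± 0.14). Tested with camera, the list had adjusted p = 0.0332, and 0.12 with an estimated correlation. The call was lost without replicate 1 (0.0638), without replicate 2 (0.0781) and without the 5 libraries nearer to another time (0.0616).

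Igfbp1 was at -5.59 ± 0.87 at 6 h (SE, edgeR adjusted p = 1.25e-07), Ppp1r3g at -6.82 ± 0.74 (8.3e-13) and Rgs16 at -4.69 ± 0.64 (2.61e-09), each lower in 10 of 10 libraries, and without replicate 1 Igfbp1 was at -2.94 and Ppp1r3g at -4.85. Fgf21, a hepatic hormone, was at -1.36 ± 0.52 (edgeR adjusted p = 0.0381, lower in 10 of 10), a call lost without replicate 1, 3, 4 or 5 (-1.55 to -1.23 over the fits that leave out 1 replicate). Chrna4, a nicotinic receptor subunit, rose by 6.31 ± 0.82 (edgeR adjusted p = 5.06e-10, higher in 10 of 10). The highest log2 fold changes were in the steroid synthesis genes Cyp11a1 (7.45 ± 1.57, edgeR adjusted p = 8.48e-05, higher in 7 of 10) and Hsd3b1 (7.19 ± 1.58, 0.00018, 6 of 10). They stood at 101.6 and 174.5 CPM in C57BL6/J water 6 h replicate 2, and their log2 fold changes were 5.34 and 5.11 without replicate 2. Summed adrenal gland transcripts were 568 CPM in that library, where the median over all libraries was 2.91 CPM. With edgeR, 4864 genes were called at 6 h, 2354 higher and 2510 lower, of which 1171 changed at least 2-fold. The libraries without the name suffix gave 4618, and 5540 were called without the 5 libraries nearer to another feeding time.

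**Figure D1:**
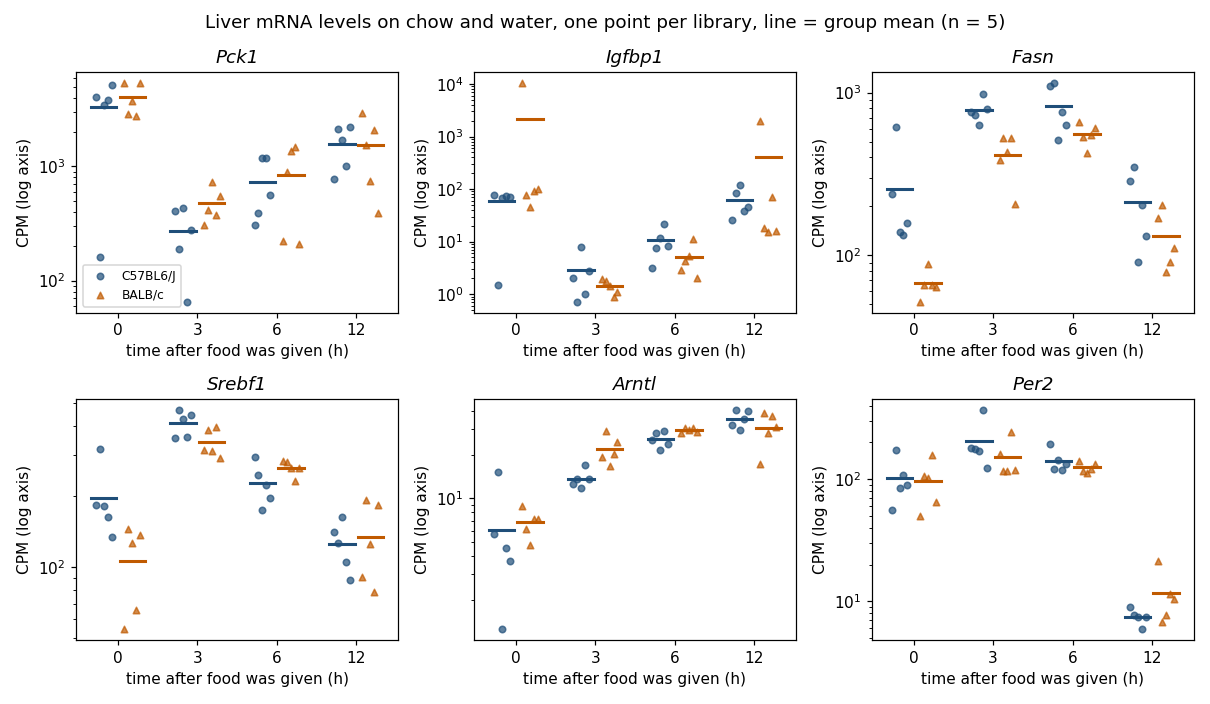
CPM per library (log axis) of Pck1, Igfbp1, Fasn, Srebf1, Arntl and Per2 against hours after feeding began in mice on water, with points for libraries and lines for the mean of 5 libraries per strain. Arntl climbs from 6.08 CPM at 0 h to 35.6 CPM at 12 h in C57BL6/J, while Pck1 drops to 274 CPM at 3 h and stands at 1573 CPM at 12 h. The C57BL6/J means at 0 h include replicate 2, which had a fed profile.

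At 12 h on water most clock genes differed from 0 h. Arntl, a core activator of the circadian clock (ENSMUSG00000055116, chromosome 7, 113207465 to 113314122), stood at 35.6 ± 4.78 CPM (SD, n = 5) in C57BL6/J and 30.5 ± 8.52 CPM in BALB/c against 6.08 ± 5.36 and 6.83 ± 1.52 CPM at 0 h. Its log2 fold change was 2.35 ± 0.16 (SE, edgeR adjusted p = 9.16e-24, higher in 10 of 10 libraries). Per2 fell from 102 ± 43.9 to 7.50 ± 1.10 CPM in C57BL6/J and from 96.0 ± 41.8 to 11.6 ± 5.87 CPM in BALB/c (-3.41 ± 0.27, edgeR adjusted p = 3.64e-20, lower in 10 of 10). Of 18 clock genes, 12 fell and 4 rose (12 and 4 adjusted over the list alone), with Dbp at -4.85 ± 0.36, Per3 at -4.12 ± 0.30 and Npas2 at 6.54 ± 0.50. The camera adjusted p was 3.81e-11, and 5.97e-08 with an estimated correlation. Most genes of sugar and fat metabolism in the panel were no longer called. Pck1 was at -1.24 ± 0.45 (edgeR adjusted p = 0.0444, lower in 10 of 10), lost without replicate 1, 3, 4 or 5 (up to -1.02). Txnip was at -0.74 ± 0.27 (edgeR adjusted p = 0.0454, lower in 8 of 10), lost without replicate 2, 3 or 5 (-0.90 to -0.56). Aqp8, a water channel, rose by 2.75 ± 0.34 (edgeR adjusted p = 4.2e-10), Spon2 by 2.63 ± 0.23 (5.67e-17) and Tubb2a by 2.39 ± 0.20 (1.43e-18), each higher in 10 of 10.

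Of the heat shock list, 8 of 13 genes fell at 12 h (2 rose and 8 fell adjusted over the list alone, Hspa1b -3.21 ± 0.41). By camera the list gave adjusted p = 6.49e-05, and 0.195 with an estimated correlation. Of 24 genes of ribosome biogenesis, 12 fell (17 adjusted over the list alone, Ncl -0.58 ± 0.09). For this list camera gave adjusted p = 1.78e-08, and 0.318 with an estimated correlation. Interferon response genes rose in 8 of 18 cases (8 adjusted over the list alone), among them Isg15 (1.32 ± 0.22). NRF2 oxidative stress genes rose in 8 of 15 cases (8 adjusted over the list alone), among them Gsr (0.52 ± 0.10). These lists had camera adjusted p = 8.87e-05 and 0.000196, and 0.548 and 0.195 with an estimated correlation. Of 26 genes of fatty acid oxidation and ketogenesis, 11 fell (12 adjusted over the list alone, Cpt1a -0.81 ± 0.18). The list had a camera adjusted p of 0.00317 (0.103 without replicate 5, 0.0635 without the 5 libraries nearer to another time), and adjusted p = 0.766 with an estimated correlation. Immediate early genes fell in 5 of 16 cases (5 fell and 1 rose adjusted over the list alone, Dusp1 -1.45 ± 0.24). As a set they had a camera adjusted p of 0.0147, and adjusted p = 0.758 with an estimated correlation.

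The lowest log2 fold changes at 12 h were in the skeletal muscle genes Mb (-6.20 ± 1.10, edgeR adjusted p = 6.94e-06), Tcap (-6.01 ± 0.99, 1.19e-06) and Myh1 (-5.70 ± 1.03, 8.85e-06), each lower in 10 of 10 libraries. The summed CPM of 10 muscle transcripts had a median of 217 at 0 h, 96.2 at 3 h, 262 at 6 h and 0.715 at 12 h, and was over 50 CPM in 6 of 10, 26 of 40, 33 of 40 and 1 of 38 libraries. With edgeR, 2974 genes were called at 12 h, 1404 higher and 1570 lower, of which 731 changed at least 2-fold. Without replicate 3 the count was 1918, in the libraries without the name suffix 2329, and without the 5 libraries nearer to another feeding time 3379.

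**Figure D2:**
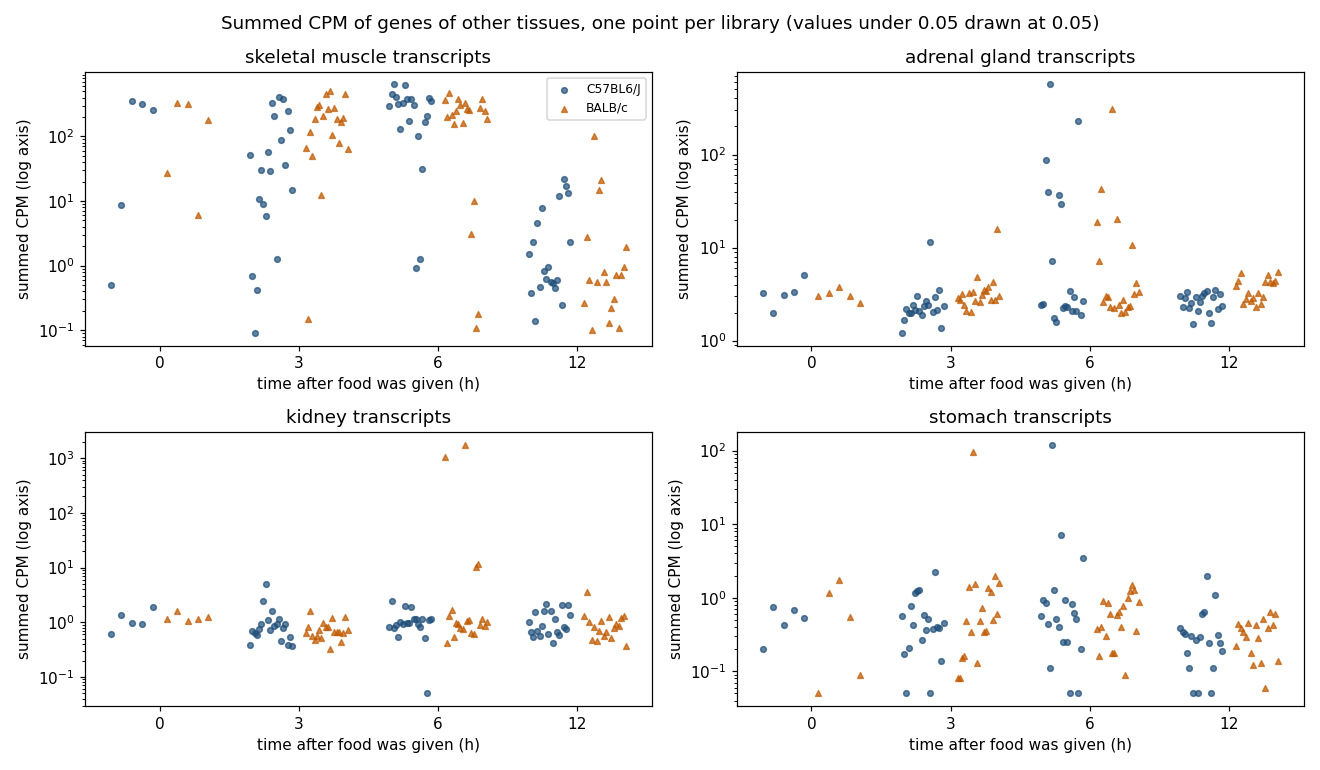
Summed CPM per library (log axis) of transcripts of skeletal muscle, adrenal gland, kidney and stomach against hours after feeding began, with values under 0.05 CPM drawn at 0.05. Muscle transcripts are over 50 CPM in 33 of 40 libraries at 6 h and in 1 of 38 at 12 h.

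The next question was how each sugar in the drink changed the liver beyond chow and water. At 3 h, genes that answer the carbohydrate-response factor ChREBP were higher with sucrose and with fructose than with water, among them Fgf21 (ENSMUSG00000030827, chromosome 7, 45613907 to 45615490). In C57BL6/J, Fgf21 was 0.286 ± 0.261 CPM (SD, n = 5) with water, 6.49 ± 4.59 with glucose, 12.7 ± 7.25 with sucrose and 7.19 ± 4.50 with fructose. In BALB/c it was 2.59 ± 2.82, 9.89 ± 8.66, 19.7 ± 10.8 and 19.3 ± 19.6 CPM. The log2 fold changes against water were 3.22 ± 0.54 for glucose (SE, edgeR adjusted p = 0.000518, higher in 9 of 10 libraries), 4.20 ± 0.55 for sucrose (4.55e-08, 10 of 10) and 3.77 ± 0.54 for fructose (5.15e-07, 9 of 10). Rgs16 was higher by 3.37 ± 0.62 with glucose (edgeR adjusted p = 0.00201, 9 of 10), 4.02 ± 0.63 with sucrose (7.26e-06, 10 of 10) and 3.92 ± 0.63 with fructose (6.62e-06, 9 of 10). Khk, the ketohexokinase, was not called with any sugar at 3 h (0.43, 0.41 and 0.46 for glucose, sucrose and fructose). The glucose calls of Fgf21 (2.73) and Rgs16 (2.96) were lost without replicate 2, and that of Rgs16 also without replicate 1 (2.70).

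Of 15 ChREBP target genes at 3 h, 3 rose with glucose (9 adjusted over the list alone), 9 with sucrose (11 adjusted over the list alone) and 9 with fructose (12 adjusted over the list alone), and 0 fell. Camera gave adjusted p = 1.89e-11, 7.15e-20 and 7.11e-13, and 0.0111, 0.000216 and 0.00946 with an estimated correlation. Dak, which phosphorylates glyceraldehyde in fructose breakdown, was at 0.92 ± 0.22 with glucose (edgeR adjusted p = 0.03, 9 of 10 libraries), 1.34 ± 0.22 with sucrose (1.91e-05, 10 of 10) and 1.15 ± 0.22 with fructose (0.00014, 9 of 10). Of 20 lipogenesis genes, 4 rose with glucose (9 adjusted over the list alone), 8 with sucrose (9 adjusted over the list alone) and 4 with fructose (8 adjusted over the list alone). Camera gave adjusted p = 1.23e-14, 1.35e-10 and 0.00208 for these, and 0.0243, 0.112 and 0.918 with an estimated correlation. Fasn was at 1.49 ± 0.31 (edgeR adjusted p = 0.0106, 10 of 10), 1.82 ± 0.32 (6.04e-05, 10 of 10) and 1.34 ± 0.31 (0.0024, 9 of 10) with glucose, sucrose and fructose. Acaca, the acetyl-CoA carboxylase, was at 1.13 ± 0.20 with sucrose (edgeR adjusted p = 7.17e-05, 10 of 10) and 0.97 ± 0.20 with fructose (0.000388, 10 of 10). The pentose phosphate list was raised with glucose (1 of 8 genes, 2 adjusted over the list alone) and with sucrose (2 of 8, 2 adjusted over the list alone). Tested with camera, glucose and sucrose gave adjusted p = 0.000193 and 0.00157, and 0.00481 and 0.0157 with an estimated correlation. The list of gluconeogenesis and FoxO1 targets had 0 of 16 genes called with glucose (1 higher adjusted over the list alone). Its median was -0.07, its mean 0.02 and the direction in camera down (adjusted p = 0.0129, adjusted p = 0.51 with an estimated correlation), a call lost without replicate 2 (0.0895) or 5 (0.248). The glucose calls of Dak (lost without replicate 1, 2, 3 or 4) and Fasn (without replicate 1, 2 or 3, 1.39 to 1.55) were not held over all 5 of these fits.

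G6pc (ENSMUSG00000078650, chromosome 11, 101367561 to 101377903) was higher with fructose at 3 h than with water. Its level was 406 ± 169 against 94.2 ± 32.0 CPM in C57BL6/J (SD, n = 5) and 400 ± 44.6 against 184 ± 63.8 CPM in BALB/c. Its log2 fold change was 1.61 ± 0.29 (SE, edgeR adjusted p = 6.66e-05, higher in 10 of 10 libraries). With sucrose it was at 0.96 ± 0.29 (edgeR adjusted p = 0.0464, 10 of 10, lost without replicate 1, 3, 4 or 5, 0.82 to 1.15), and with glucose at -0.51 (0.985). Hcn3, an ion channel gene, rose with sucrose (2.59 ± 0.38, edgeR adjusted p = 1.41e-06, 10 of 10) and fructose (2.38 ± 0.38, 4.9e-06, 9 of 10). The cytoskeletal actin Actg1 fell by 1.46 on the log2 scale with sucrose (SE 0.28, 0.000235, lower in 10 of 10) and by 1.97 with fructose (SE 0.28, 3.82e-07, 10 of 10) by edgeR, and the linker histone Hist1h1c by 1.35 (0.000259) and 1.71 (1.63e-06). Cdcp1 fell by 1.74 with fructose (SE 0.26, edgeR adjusted p = 1.16e-06, 10 of 10). Of 24 genes of ribosome biogenesis, 12 fell with fructose (14 adjusted over the list alone), among them Rrp9 (-0.64 ± 0.12), and 2 with sucrose (12 adjusted over the list alone). Fructose and sucrose had camera adjusted p = 6.84e-13 and 1.46e-09, and 0.104 and 0.241 with an estimated correlation. With glucose the genes called lower at 3 h included Gnpda1, a glucosamine 6-phosphate deaminase (edgeR adjusted p = 0.00201, lower in 10 of 10), at -0.69 ± 0.13, lost without replicate 2 or 3.

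With glucose at 3 h, Egr1 (3.22 ± 0.73, SE, edgeR adjusted p = 0.0229, higher in 4 of 10 libraries), Cxcl1 (2.99 ± 0.67, 0.0205, 7 of 10) and the immediate early list (1 of 16 genes higher, 6 adjusted over the list alone) rested on C57BL6/J glucose 3 h replicate 1, in which Egr1 stood at 556 CPM and Cxcl1 at 593 CPM. By camera the list gave adjusted p = 0.013, and adjusted p = 0.526 with an estimated correlation. Without replicate 1, Egr1 was at 0.55, Cxcl1 at 0.51, and the list ran the other way with a camera adjusted p of 0.389. The call of Egr1 was lost in all 5 fits that leave out 1 replicate number, and that of Cxcl1 in those without replicate 1, 2, 3 or 5.

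At 3 h edgeR called 32 genes with glucose (28 higher, 4 lower), 493 with sucrose (278 and 215) and 1133 with fructose (569 and 564) against water. In the libraries without the name suffix the counts were 1, 107 and 399. Leaving out replicate 1, 2 or 3 left 2, 2 and 3 genes with glucose, leaving out 1, 3 or 5 left 272, 160 and 274 with sucrose, and leaving out 2, 3 or 5 left 674, 640 and 724 with fructose. Without the 5 libraries nearer to another feeding time they were 46, 572 and 1082.

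**Figure D3:**
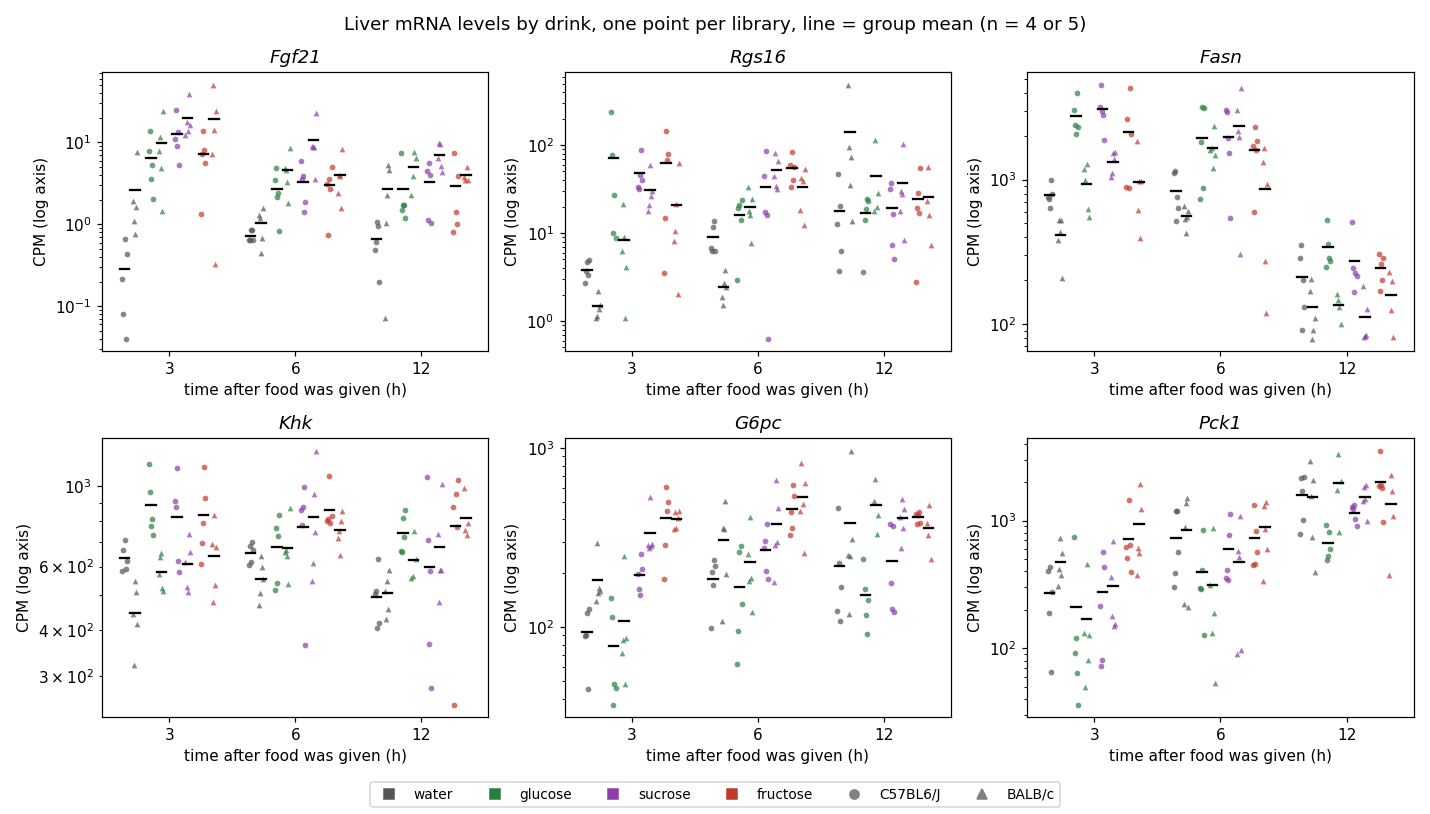
CPM per library (log axis) of Fgf21, Rgs16, Fasn, Khk, G6pc and Pck1 by drink and hours after feeding began in both strains, with 4 or 5 libraries per group. At 3 h in C57BL6/J, mean Fgf21 is 0.286 CPM with water and 12.7 CPM with sucrose, and mean G6pc is 94.2 CPM with water and 406 CPM with fructose.

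Against water at 6 h, 9 of 25 cholesterol synthesis genes fell with fructose (23 adjusted over the list alone, median log2 fold change -0.77). BALB/c fructose replicates 3 and 4 lay nearest to 3 h and 0 h, which can lower these genes. Hmgcs1, the cytosolic HMG-CoA synthase (ENSMUSG00000093930, chromosome 13, 119690462 to 119708086), fell by 1.38 (SE 0.26, edgeR adjusted p = 0.00077), Mvk by 1.00 (SE 0.19, 0.000773) and Fdft1 by 0.90 (SE 0.17, 0.000878), each lower in 10 of 10 libraries. The list had camera adjusted p = 8.73e-31, and 0.0153 with an estimated correlation. With sucrose 4 of the 25 fell (7 adjusted over the list alone, Mvk -0.85 ± 0.19, not called without replicate 4 or 5). For this list camera gave adjusted p = 1.74e-11, and 0.285 with an estimated correlation. ChREBP targets rose in 5 of 15 cases with fructose (10 adjusted over the list alone), 4 with sucrose (10 adjusted over the list alone) and 1 with glucose (5 adjusted over the list alone). Camera gave adjusted p = 2.92e-11, 5.73e-09 and 0.000907 for these, and 0.0153, 0.0787 and 0.392 with an estimated correlation. Rgs16 rose by 3.18 ± 0.60 with fructose (edgeR adjusted p = 0.000868, higher in 10 of 10) and 3.15 ± 0.60 with sucrose (0.00082, 9 of 10), and Fgf21 by 2.78 ± 0.52 with sucrose (0.000611, 10 of 10).

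Lipogenesis genes rose at 6 h in 4 of 20 cases with glucose (12 adjusted over the list alone) and 8 with sucrose (10 higher and 1 lower adjusted over the list alone). Camera gave adjusted p = 1.45e-08 and 1.9e-07, and 0.341 and 0.285 with an estimated correlation. Acaca rose by 1.20 ± 0.20 with glucose (SE, edgeR adjusted p = 0.000404, higher in 10 of 10 libraries) and 1.27 ± 0.20 with sucrose (2.84e-05, 9 of 10), and Fasn by 1.67 ± 0.31 with sucrose (0.000634, 8 of 10). With glucose, Derl3 of endoplasmic reticulum protein degradation rose by 2.25 ± 0.49 (edgeR adjusted p = 0.00873, 10 of 10, lost without replicate 2 or 3, 1.77 to 2.41). The mitochondrial carrier Slc25a34 fell by 0.97 (SE 0.20, edgeR adjusted p = 0.00688, lower in 10 of 10, lost without replicate 1 or 5). The unfolded protein response list was raised with glucose (1 of 20, 9 adjusted over the list alone, median 0.39). As a set they had a camera adjusted p of 1.37e-07, and 0.392 with an estimated correlation. Genes of amino acid catabolism were lower with all 3 sugars, 2 of 21 with glucose (6 adjusted over the list alone, camera adjusted p = 5.2e-10), 2 with sucrose (4 adjusted over the list alone, 5.9e-09) and 1 with fructose (5 adjusted over the list alone, 3.87e-10). These had adjusted p = 0.341, 0.285 and 0.233 with an estimated correlation. Hal, which degrades histidine, was at -0.54, -0.53 and -0.66 with glucose, sucrose and fructose. These edgeR calls were lost without replicate 2 or 5, that for glucose also without 1 or 3, and that for sucrose also without 3 or 4.

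Xenobiotic metabolism genes were lower with sucrose at 6 h (1 of 22, 10 adjusted over the list alone), led by Cyp1a2 (-1.07 ± 0.22, SE, edgeR adjusted p = 0.00216, lower in 10 of 10 libraries, -0.77 and not called without replicate 2). Tested with camera, the list had adjusted p = 2.1e-08, and 0.0906 with an estimated correlation. Acute phase genes were higher with sucrose (2 of 22, 9 adjusted over the list alone), with Saa2 at 4.71 ± 1.08 (edgeR adjusted p = 0.0107), higher in 4 of 10 libraries, lost without replicate 4 (2.86) or 5. Neutrophil markers had a mean log2 CPM of -0.69 ± 1.24 (SD, n = 5) in BALB/c with sucrose and -2.15 ± 0.38 with water at 6 h. By camera the acute phase list gave adjusted p = 2.53e-05 (0.0847 without replicate 4), and adjusted p = 0.401 with an estimated correlation. With glucose, Cxcl1 (2.84 ± 0.66, edgeR adjusted p = 0.0157, 8 of 10, lost without replicate 1, 2 or 5) and the same list (2 of 22, 7 adjusted over the list alone) were called, and without replicate 1 the list had a camera adjusted p of 0.39. With all replicates camera gave glucose adjusted p = 0.0021, and adjusted p = 0.518 with an estimated correlation. Neutrophil markers were the highest of all libraries in C57BL6/J glucose 6 h replicate 1. Acsm2 fell with sucrose (-3.34 ± 0.69, edgeR adjusted p = 0.00221, 9 of 10) and fructose (-3.03 ± 0.67, 0.00594, 10 of 10), at -0.57 and -0.19 without replicate 1, and these calls were also lost without replicate 5. In BALB/c water 6 h replicate 1 it was at 81.3 CPM beside 1058 CPM of summed kidney transcripts. At 6 h edgeR called 153 genes with glucose (92 higher, 61 lower), 193 with sucrose (98 and 95) and 207 with fructose (98 and 109). Leaving out 1 replicate number gave 24 (without 5) to 123 (without 4), 35 (without 5) to 195 (without 1) and 59 (without 5) to 155 (without 4). The libraries without the name suffix gave 18, 50 and 16. Without the 5 nearer to another time these were 253, 316 and 277 (fructose kept 156 of 207).

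At 12 h few genes separated a sugar from water. The fructose metabolism list was raised with fructose (1 of 10 genes, 3 adjusted over the list alone). The list had a camera adjusted p of 2.74e-07, and 0.0558 with an estimated correlation. With sucrose, Dnaic1, an axonemal dynein gene, was higher in 10 of 10 libraries (1.57 ± 0.29, SE, edgeR adjusted p = 0.00682, lost without replicate 1, 3 or 5, 1.48 to 1.62). With glucose, Nudt7, a peroxisomal CoA hydrolase, was higher in 8 of 9 (1.43 ± 0.24, edgeR adjusted p = 0.00052, lost without replicate 2) and the transporter Slco1a4 lower in 9 of 9 (-1.20 ± 0.21, 0.000603, lost without replicate 2). Male-biased growth hormone responsive genes were raised with glucose (1 of 12, 3 adjusted over the list alone, median 0.57). As a set they had a camera adjusted p of 2.18e-17, and 0.00801 with an estimated correlation. Amino acid catabolism was lowered with glucose (0 of 21 genes called, 8 adjusted over the list alone), with Oat at -0.83 ± 0.20 (edgeR adjusted p = 0.0677, lower in 9 of 9). Xenobiotic metabolism was lowered as well (1 of 22, 7 adjusted over the list alone). These lists had camera adjusted p = 1.35e-19 and 7.71e-09, and 0.0177 and 0.0357 with an estimated correlation. The serum amyloid genes Saa1, Saa2 and Saa3, members of a family of similar sequences, were at 4.31, 5.18 and 3.20 with glucose (edgeR adjusted p = 0.0456, 0.0262 and 0.0342, higher in 8, 8 and 6 of 9), and at 1.96, 2.48 and 1.05 without replicate 1, and the calls were also lost without replicate 2, 3 or 5. With edgeR, 11 genes were called with glucose (7 higher, 4 lower), 1 with sucrose and 1 with fructose. At an unadjusted p under 0.05 there were 901, 734 and 714, and DESeq2 called 65, 28 and 29. Leaving out 1 replicate number gave 0 to 26 genes with glucose, 0 to 1 with sucrose and 0 to 3 with fructose, the libraries without the name suffix 0, 0 and 0, and leaving out the 5 libraries nearer to another time 9, 1 and 2.

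**Figure D4:**
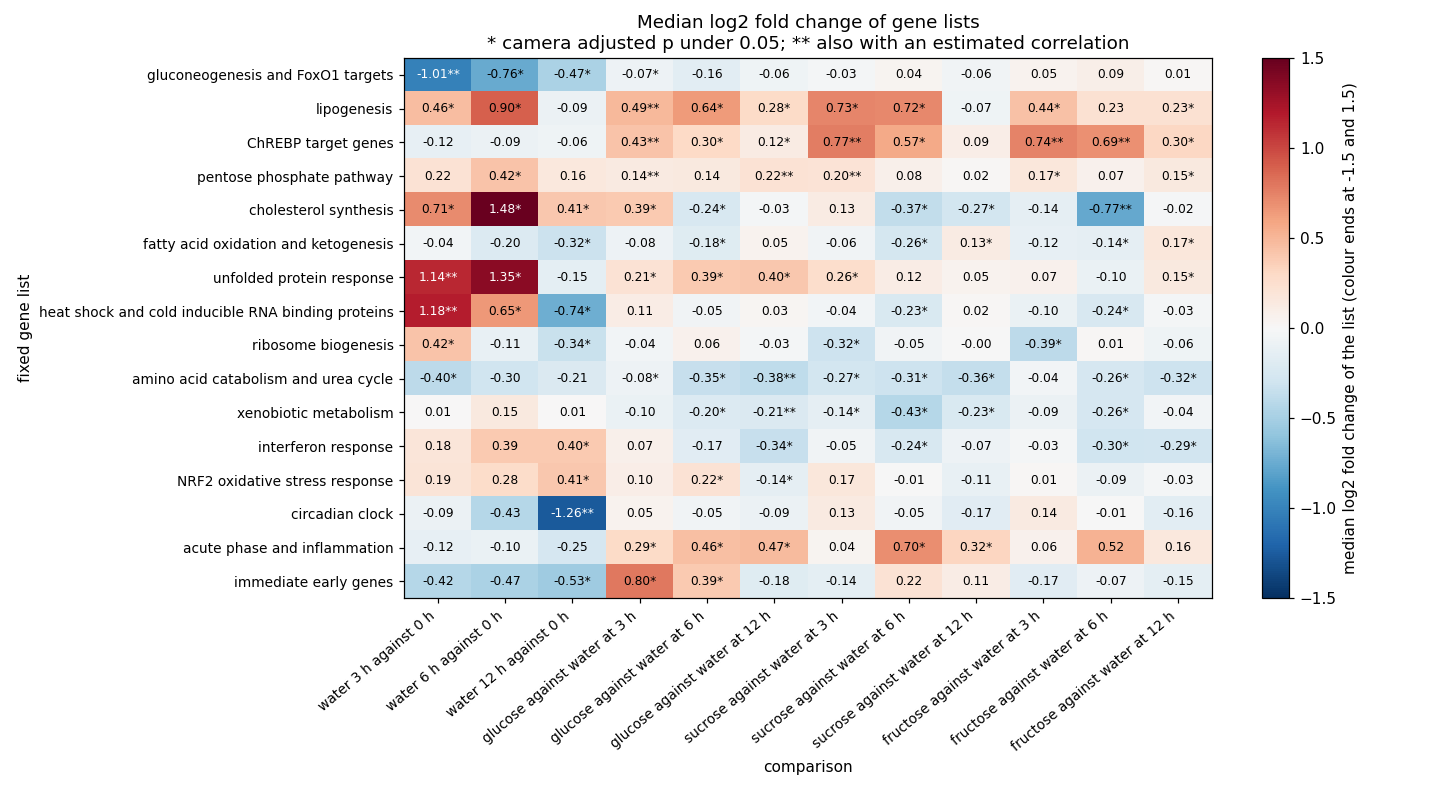
Median log2 fold change of 16 gene lists (lines) in 12 contrasts (columns), with 1 star for a camera adjusted p under 0.05 and 2 stars where the call also held with an estimated correlation. Cholesterol synthesis has a median of 1.48 at 6 h on water against 0 h, and of -0.77 with fructose against water at 6 h.

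The sugars were then compared with one another at matched times. Fructose and glucose differed at 3 h in 2 genes of glucose production, G6pc and Pck1. G6pc was higher with fructose by 2.13 ± 0.30 on the log2 scale (SE, 95% interval 1.53 to 2.73, edgeR adjusted p = 9.12e-07, higher in 10 of 10 libraries). Pck1 was higher by 2.12 ± 0.47 (1.20 to 3.05, edgeR adjusted p = 0.00359, 10 of 10, 1.71 and not called without replicate 4). BALB/c fructose replicate 4 had a fasted profile, which can raise both genes (in C57BL6/J alone 2.37 ± 0.43 and 1.78 ± 0.65). They were the 2 called of 16 genes of gluconeogenesis and FoxO1 targets (2 adjusted over the list alone, median 0.12). Tested with camera, the list had adjusted p = 0.00129 (0.0754 without replicate 5), and 0.522 with an estimated correlation. No difference was called for Fgf21 (interval -0.35 to 1.46), Fasn (-0.76 to 0.46) or Khk (-0.30 to 0.35). Of 25 genes of cholesterol synthesis, 6 were lower with fructose (13 adjusted over the list alone), among them Mvk (-0.83 ± 0.19, not called without replicate 4). Of 24 genes of ribosome biogenesis, 4 were lower (12 adjusted over the list alone). These lists had camera adjusted p = 1.27e-15 and 1.62e-13, and 0.299 and 0.281 with an estimated correlation. Egr1 (-3.90 ± 0.77) and Cxcl10 (-2.86 ± 0.57) were lower with fructose (edgeR adjusted p = 0.00107 and 0.00128, 10 and 9 of 10), and at -1.17 and -0.34 without replicate 1, where neither was called. At 6 h, G6pc was higher with fructose (1.32 ± 0.29, interval 0.74 to 1.90, edgeR adjusted p = 0.0188, 10 of 10, lost without replicate 2 or 5). So was Cyp7a1, the rate-limiting enzyme of bile acid synthesis (1.33 ± 0.32, interval 0.70 to 1.97, edgeR adjusted p = 0.0289, 9 of 10, lost without replicate 1, 2, 3 or 5). Of 20 genes of the unfolded protein response, 1 was lower with fructose at 6 h (15 adjusted over the list alone, median -0.45). Tested with camera, the list had adjusted p = 1.48e-16, and 0.133 with an estimated correlation.

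The renal transcripts Klk1 (-5.09 ± 0.94, SE, edgeR adjusted p = 0.0069, lower in 10 of 10 libraries) and Acsm2 (-3.43 ± 0.68, 0.0134, 10 of 10) were lower with fructose than glucose at 6 h. In BALB/c glucose 6 h replicate 3 they stood at 128.9 and 190.6 CPM beside 1768 CPM of summed kidney transcripts, and without replicate 3 their values were 0.55 and 0.18. The call of Acsm2 was also lost without replicate 5. For fructose against glucose edgeR called 396 genes at 3 h (182 higher, 214 lower), 43 at 6 h (16 and 27) and 0 at 12 h, where 406 had an unadjusted p under 0.05 and DESeq2 called 17. Leaving out replicate 2, 3 or 4 left 183, 158 and 102 at 3 h, and leaving out replicate 2, 3 or 5 left 26, 1 and 1 at 6 h. The libraries without the name suffix gave 99, 3 and 0, and leaving out the 5 libraries nearer to another feeding time 388, 20 and 0.

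Sucrose and glucose differed at 3 h in G6pc, higher with sucrose by 1.47 ± 0.29 (SE, 95% interval 0.89 to 2.06, edgeR adjusted p = 0.0094, 10 of 10 libraries, lost without replicate 4 or 5). Fbxl20 was higher with sucrose too (0.82 ± 0.15, interval 0.53 to 1.11, edgeR adjusted p = 0.00249, 10 of 10, lost without replicate 5). At 6 h only Klk1 and Acsm2 were called (-5.42 ± 0.96 and -3.75 ± 0.70, edgeR adjusted p = 0.00268 and 0.00384, 10 and 9 of 10), at 0.32 and -0.07 without replicate 3, and that of Acsm2 was also lost without replicate 2 or 5. At 12 h only Cyp7a1 was called (1.77 ± 0.34, interval 1.10 to 2.43, edgeR adjusted p = 0.0132, 10 of 10, lost without replicate 1, 2, 3 or 5, 1.56 to 1.93). The counts were 36 (15 higher, 21 lower), 2 and 1. They ranged from 0 (without replicate 5) to 35 (without replicate 1), 0 to 7 and 0 to 1 over the fits without 1 replicate number, and were 7, 0 and 0 in the libraries without the name suffix and 62, 2 and 1 without the 5 libraries nearer to another feeding time.

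Between fructose and sucrose edgeR called 0 genes at 3, 6 and 12 h, where 511, 402 and 243 had an unadjusted p under 0.05 and DESeq2 called 7, 2 and 12. At 3 h the interval of the log2 difference was 0.60 to 2.42 for Pck1, 0.08 to 1.23 for G6pc, -1.32 to 0.47 for Fgf21, and -1.09 to 0.12 for Fasn, and at 6 h -1.49 to -0.27 for Fasn and -1.69 to 0.17 for Fgf21, where the intervals are not adjusted for the number of genes. Those of Pck1 and G6pc at 3 h and of Fasn at 6 h leave out 0, so a difference is not excluded. Each includes BALB/c fructose replicate 4, with a fasted profile. The libraries without the name suffix gave 0, 0 and 0.

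**Figure D5:**
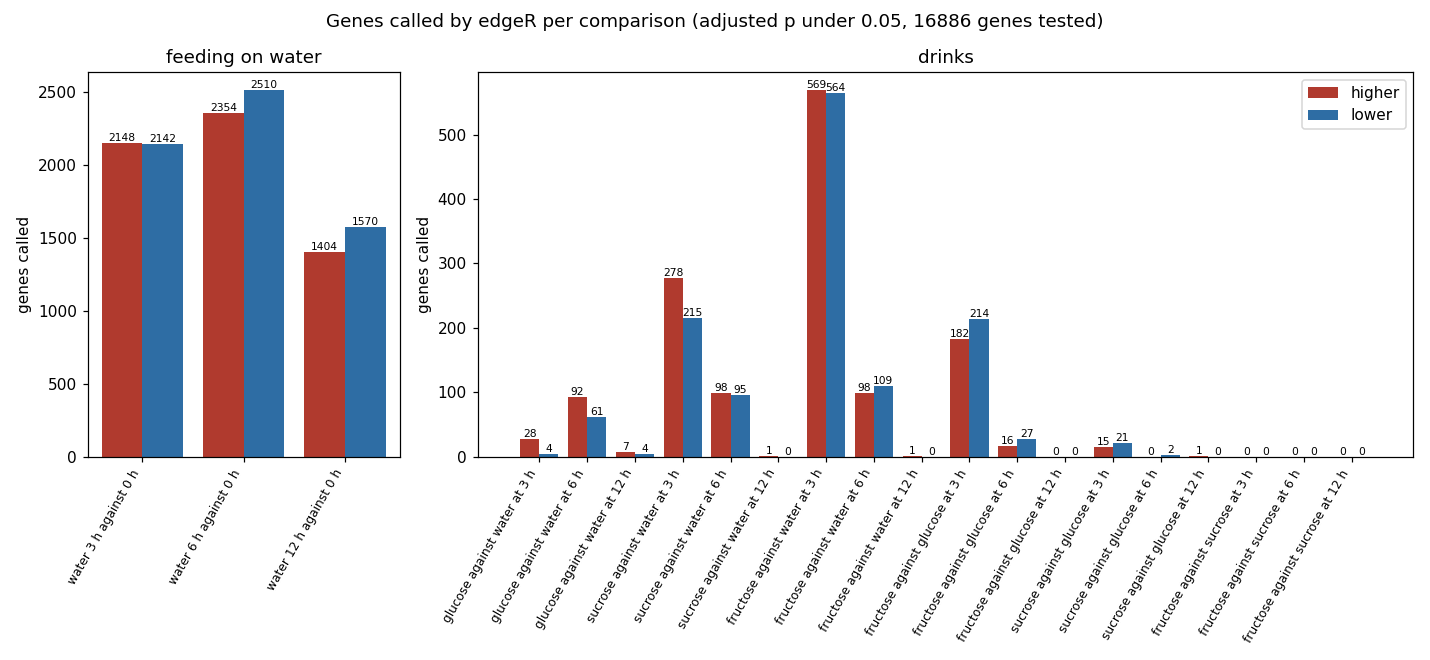
Genes called higher and lower by edgeR in each contrast among 16886 tested. Feeding on water accounts for 4290, 4864 and 2974 genes at 3, 6 and 12 h, and the sugars at 3 h for 32 with glucose, 493 with sucrose and 1133 with fructose.

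The strains were compared at 0 h, 5 libraries each, where C57BL6/J replicate 2 had a fed profile, which can raise genes of sterol and fat synthesis in that strain. Without replicate 2, Sqle was at -3.50 and Cyp51 at -3.02. Genes of cholesterol synthesis were lower in BALB/c in 19 of 25 cases (21 adjusted over the list alone), with a median log2 fold change of -1.26. Sqle was at -3.85 ± 0.50 (SE, edgeR adjusted p = 8.7e-10, lower in 5 of 5 BALB/c libraries) and Cyp51 at -3.10 ± 0.39 (1.32e-10, 5 of 5). Camera gave adjusted p = 3.24e-17, and 0.286 with an estimated correlation. Of 20 lipogenesis genes, 6 were lower in BALB/c (8 adjusted over the list alone). Fasn was at -1.93 ± 0.45 (edgeR adjusted p = 0.000671, 5 of 5), and -1.32 and not called without replicate 2. By camera the lipogenesis list gave adjusted p = 0.00129 (0.0552 without replicate 1), and 0.923 with an estimated correlation. Pericentral hepatocyte markers were lower in 5 of 14 cases (7 adjusted over the list alone, Slc1a2 -1.31 ± 0.17). For this list camera gave adjusted p = 0.000291, and 0.286 with an estimated correlation. Of 20 genes of the unfolded protein response, 11 were lower (13 adjusted over the list alone). The list had a camera adjusted p of 0.00129 (0.218 without replicate 2, 0.185 without the 5 libraries nearer to another time), and 0.923 with an estimated correlation. Pdk4, which restrains glucose oxidation, was higher in BALB/c by 2.54 ± 0.33 (edgeR adjusted p = 3.42e-10, 5 of 5), and Txnip by 1.69 ± 0.39 (0.000681, 5 of 5). Igfbp1 was at 5.23 ± 1.20 (edgeR adjusted p = 0.000528, 4 of 5), and 0.55 and not called without replicate 1.

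C1rb, a complement protease (7.91 ± 0.66, SE, edgeR adjusted p = 7.87e-19, higher in 5 of 5), and Hist1h2al, a histone gene (7.66 ± 0.68, 1.6e-17, 5 of 5), were among the highest in BALB/c at 0 h. Adra2a was also among them by edgeR (adjusted p = 1.5e-10, 5 of 5), with 140.4 CPM in BALB/c water 0 h replicate 1, 0.139 to 0.395 CPM in the other BALB/c libraries and 0 CPM in 5 of 5 C57BL6/J libraries. The lowest were the major urinary protein genes Mup10, Mup12 and Mup15 (edgeR adjusted p = 3.29e-18, 1.55e-13 and 2.37e-12, lower in 5 of 5), members of a family of near-identical copies on chromosome 4 whose counts are uncertain. Between the strains at 0 h edgeR called 2753 genes, 1457 higher and 1296 lower in BALB/c, 1421 of them at least 2-fold. Leaving out replicate 1 left 1805, the libraries without the name suffix gave 2429, and 2559 were called without the 5 libraries nearer to another feeding time.

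Whether the strains answered differently was tested as an interaction. On water, 107 genes differed between the strains in their course over time, with 1567 at an unadjusted p under 0.05. Nr1d1, a clock repressor, was at -1.59 ± 0.39 at 3 h in C57BL6/J and -2.87 ± 0.42 in BALB/c, and at 12 h stood at -0.70 ± 0.38 in C57BL6/J and 1.53 ± 0.38 in BALB/c (SE, edgeR adjusted p = 0.000451, 0.054 without replicate 1 and 0.163 in the libraries without the name suffix). Cdpf1 was at 0.47 ± 0.18 and -1.13 ± 0.19 at 3 h in C57BL6/J and BALB/c (edgeR adjusted p = 5.81e-05). Amica1 and Mpzl2, which lie side by side on chromosome 9, were called as well (1.05e-05 and 1.24e-05 by edgeR) and stood at 357 and 1866 CPM in BALB/c water 0 h replicate 1, with the next highest library at 8.54 and 83.2 CPM. Without replicate 1 their adjusted p was 0.297 and 0.72. Leaving out replicate 1, 2, 3 or 5 left 7, 24, 44 and 42 genes, and leaving out BALB/c water 0 h replicate 1 alone left 33. The libraries without the name suffix gave 11, and 134 were called without the 5 libraries nearer to another feeding time.

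For the drinks, edgeR called 8 genes at 3 h, 30 at 6 h and 0 at 12 h in the interaction with strain, where 406, 716 and 333 had an unadjusted p under 0.05 and DESeq2 called 8, 36 and 0. At 3 h Ripk2, Rnd1, Cxcl10 and Tnfaip3 of inflammatory signalling (edgeR adjusted p = 0.0017, 0.0017, 0.00741 and 0.0226) were at 130.8, 207.2, 437.5 and 226.3 CPM in C57BL6/J glucose 3 h replicate 1, and each had an adjusted p of 1 without replicate 1. At 6 h Lcn2, an acute phase protein (edgeR adjusted p = 0.000802), was at 3.08 ± 1.09 in C57BL6/J and 0.13 ± 1.08 in BALB/c with glucose, and at -0.92 ± 1.06 and 5.28 ± 1.22 with sucrose. With fructose it was at -1.16 ± 1.06 and 4.62 ± 1.18. Mt1, a metallothionein, was at -0.26 ± 0.78 in C57BL6/J and 4.00 ± 0.88 in BALB/c with fructose (edgeR adjusted p = 0.00105, 0.119 without replicate 1). Both BALB/c fructose values include replicate 4, with a fasted profile. There Lcn2 was at 488.8 CPM (median of all libraries 5.95) and Mt1 highest of all at 6211 CPM (56.99 to 460.8 CPM in the other 4). Without the 5 libraries nearer to another time the adjusted p of Mt1 was 0.0158. Leaving out 1 replicate number gave 1 (without 1) to 9 (without 4) genes at 3 h and 8 (without 5) to 33 (without 1) at 6 h. The libraries without the name suffix gave 3, 2 and 0, and leaving out the 5 libraries nearer to another time 7, 24 and 0. Across the 9480 genes with a mean CPM of at least 5, the sugar effects in the strains, which share no library, correlated across genes with Pearson's r between 0.222 (fructose at 12 h) and 0.547 (fructose at 3 h). Over all 16886 genes tested r was lower, between -0.05 (fructose at 12 h) and 0.264 (fructose at 3 h), where genes are not independent replicates.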

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

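The tests on C57BL6/J water 0 h replicate 2 were chosen after its profile had been seen, the bounds from the clock positions at 0 h and from leaving out replicates after the values they judge had been seen, and the models that leave out the 5 libraries nearer to another feeding time, leave out BALB/c water 0 h replicate 1 or keep the libraries without the name suffix were added after the data were examined. Dixon's gap test was applied to 494 groups of 4 or 5 libraries, the 19 panel genes in each group of strain, drink and time. In 37 of them 1 library lay far from the others, where chance alone gives about 1 in 20 groups. Of the 37, 28 are given here.

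In the fasted mice, C57BL6/J water 0 h replicate 2 was lowest for Pck1 at 160 CPM (others 3490 to 5150) and Igfbp1 at 1.47 CPM (66.8 to 76.1). BALB/c water 0 h replicate 1 was highest for Igfbp1 at 10600 CPM (46 to 99.5) and lowest for Khk at 146 CPM (497 to 606). On water at 3 h, BALB/c replicate 2 was highest for G6pc at 296 CPM (140 to 167).

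With glucose at 3 h, C57BL6/J replicate 1 was highest for Igfbp1 at 735 CPM (1.01 to 4.36). Replicate 4 was lowest for Nnt in both strains, at 39.1 CPM (48.5 to 52.5) in C57BL6/J and 105 CPM (144 to 158) in BALB/c. With glucose at 6 h, C57BL6/J replicate 1 was lowest for Rgs16 at 2.9 CPM (14.2 to 23.7) and replicate 5 for Arntl at 17.9 CPM (26.9 to 27.7), while BALB/c replicate 4 was highest for Arntl at 37.5 CPM (24.7 to 26.8). With glucose at 12 h, C57BL6/J replicate 1 was highest for Fgf21 at 7.4 CPM (1.19 to 1.73) and lowest for Rgs16 at 3.61 CPM (14.1 to 24.4).

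With sucrose at 3 h, BALB/c replicate 3 was highest for G6pc at 530 CPM (277 to 291). Per2 was highest at 342 CPM in C57BL6/J replicate 2 (121 to 157) and at 249 CPM in BALB/c replicate 4 (109 to 135). With sucrose at 6 h, C57BL6/J replicate 5 was lowest for Khk at 364 CPM (779 to 993), and BALB/c replicate 4 for Pklr at 55.4 CPM (195 to 273).

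With fructose, BALB/c 6 h replicate 4 was lowest for Arntl at 15.2 CPM (25.6 to 29.3). C57BL6/J 6 h replicate 2 was lowest for Srebf1 at 160 CPM (299 to 377) and Fasn at 596 CPM (1610 to 2310), and replicate 3 highest for Khk at 1070 CPM (792 to 828). At 12 h, C57BL6/J replicate 2 was highest for Igfbp1 at 362 CPM (60.7 to 102) and Nnt at 62.3 CPM (39 to 44.4) and lowest for Khk at 250 CPM (772 to 1040), and replicate 5 highest for Srebf1 at 157 CPM (119 to 125). BALB/c replicate 5 was lowest for Pklr at 86.6 CPM (242 to 289), and replicate 1 highest for Txnip at 55.1 CPM (40.5 to 42.4).

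By edgeR's interaction test the strains' course on water differed in Amica1 (adjusted p = 1.05e-05), Mpzl2 (1.24e-05), Cdpf1 (5.81e-05), Nr1d1 (0.000451) and Fam222a (0.00186), and of the panel in Igfbp1 (0.0315), Txnip (0.0109) and Rgs16 (0.0296). Igfbp1 and Txnip peaked in BALB/c water 0 h replicate 1 and Rgs16 in that of 12 h, which can carry these calls. At 3 h the log2 fold changes in C57BL6/J and BALB/c were 0.09 and -7.15 for Amica1, -0.08 and -3.34 for Mpzl2, and -0.12 and -1.69 for Fam222a. Without replicate 1 the adjusted p was 0.297 for Amica1, 0.72 for Mpzl2, 0.054 for Nr1d1 and 0.0842 for Fam222a, and the call of Cdpf1 was kept in the fits without 1 replicate.

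In the drinks the strains differed by the same test at 3 h in Xist (adjusted p = 8.44e-05), Ripk2 (0.0017), Rnd1 (0.0017), Cxcl10 (0.00741) and Tnfaip3 (0.0226), and at 6 h in Lcn2 (0.000802), Mt1 (0.00105), Saa2 (0.00151), Acsm2 (0.00151) and Star (0.00151). Xist had an adjusted p of 1 without replicate 5, and Ripk2, Rnd1, Cxcl10 and Tnfaip3 had 1 without replicate 1. Mt1 had 0.119 without replicate 1 and Star 0.717 without replicate 2. With sucrose the log2 fold change of Xist was -0.64 in C57BL6/J and 9.04 in BALB/c, and with glucose that of Cxcl10 was 5.70 and -0.45. With fructose at 6 h Saa2 was at -0.57 in C57BL6/J and 8.41 in BALB/c, which includes replicate 4 at 8875 CPM (2.787 to 8.762 CPM in the other 4), Acsm2 at -0.79 and -5.27, and Star at -3.49 and 2.13. These 2 follow transcripts of other organs: Acsm2 was at 81.26 CPM in BALB/c water 6 h replicate 1, with 1058 CPM of summed kidney transcripts. Star was at 155.1 CPM in C57BL6/J water 6 h replicate 2 and 59.93 CPM in BALB/c fructose 6 h replicate 2, with 568.2 and 306.5 CPM of summed adrenal transcripts.

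C57BL6/J water 0 h replicate 2 had a fed profile, correlating at -0.132 with its own time and 0.814 with 3 h. A swap with another C57BL6/J library is argued against, since 0 others lay nearest the 0 h mean. On a scale with 0 at the 0 h mean and 1 at the 3 h mean its clock genes lay at 1.131, where the other 4 C57BL6/J libraries at 0 h lay at -0.53 to -0.173 and those at 3 h at 0.697 to 1.518. A wrong label, of a mouse killed after feeding began, is consistent with this. A mouse killed at 0 h that had eaten during the fast cannot be told apart from it (metabolic position 0.944): the clock position was to separate these, but every fed group was also later in the day, and no biological explanation was tested beyond this meal.

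BALB/c fructose replicate 4 had a fasted profile at 3 h and at 6 h, nearest the 0 h mean at both times. At 3 h its clock genes lay at 0.336 and its metabolic genes at 0.572 (other BALB/c libraries at 3 h 0.803 to 1.302 and 0.876 to 1.22). At 6 h they lay at 0.677 and 0.406 (others 0.835 to 1.209 and 0.651 to 1.464). The 5 BALB/c libraries at 0 h had clock positions of -0.039 to 0.131 on the 3 h scale and -0.078 to 0.089 on the 6 h scale. A wrong label, of a mouse killed at 0 h, is argued against at both times by a bound of 3 SD above the mean of these 5 (0.252 and 0.214), set after the positions had been seen, but is not excluded by the bound set beforehand, 0.75. A mouse that had eaten little cannot be told apart from other causes, since the clock positions lie below the 0.75 set for it, while the metabolic position at 6 h is as low as it needs. No biological explanation was tested beyond this meal.

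Fructose against water at 3 h ran weakly against the feeding response, taken as water 6 h against 0 h, which shares no library with it: Pearson's r across genes, which are not independent replicates, was -0.077, where glucose gave 0.107 and sucrose 0.098. In BALB/c alone these were -0.09, -0.009 and 0.008, and in C57BL6/J alone -0.054, 0.146 and 0.046. Leaving out 1 replicate number shifted r by up to 0.033, 0.051 and 0.073, with fructose always lowest but each r weak. By the bound set beforehand, r below -0.1, neither the BALB/c library with a fasted profile (r = -0.054 in C57BL6/J alone) nor the batch of the name suffix (r = -0.079 with the suffix as a covariate) is excluded. By a bound set after r had been seen, each is argued against as the whole cause: in the model of both strains, leaving out 1 replicate number gave -0.108 to -0.044, a shift of at most 0.033. In that model r = -0.08 without the 5 libraries nearer to another feeding time, of which that library is one, and r = -0.079 with the suffix lie further below 0. A part of each in the pattern stays open. A smaller or slower meal cannot be told apart from an effect of fructose. Lipogenesis genes, higher at 3 h than at 0 h on water, were higher again with fructose (median 0.444 on the log2 scale), which had been set beforehand to exclude it. These list calls were lost with an estimated correlation (adjusted p = 0.911 and 0.918), and of the 7 genes called higher on water 2 were called higher with fructose. The list was higher with glucose and sucrose too (camera adjusted p = 1.23e-14 and 1.35e-10, and 0.0243 and 0.112 with an estimated correlation), so the sugar itself can raise them whatever was eaten. No biological explanation was tested for this pattern.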

How the results depend on the processing

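The tests added after the data were examined were those in the libraries without the name suffix, without the 5 libraries nearer to another feeding time, and without BALB/c water 0 h replicate 1. In every group of counts below, feeding and each sugar are given in the order 3, 6 and 12 h where all 3 times are named, and the count with edgeR and all libraries is in the report. RLE size factors kept all counts within 1.5 times. Of 1053 values of named genes, 1045 kept their direction and their side of the threshold with RLE size factors, 1017 without the filter on low counts and 1020 with the name suffix as a covariate. DESeq2 kept 956 of 1010, with 51 more called. Models of the libraries of the contrast alone kept 930 of 1040, libraries without the name suffix 878 of 1053, and the model without the 5 libraries nearer to another feeding time 980 of 1053. Leaving out replicates 1 to 5 kept 893 of 1051 and 928, 926, 958 and 921 of 1053, and leaving out BALB/c water 0 h replicate 1 kept 1005.

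DESeq2 called 59, 270 and 65 genes with glucose, 329 with sucrose at 6 h, and 28 with sucrose and 29 with fructose at 12 h. It called 86 and 17 for fructose against glucose at 6 and 12 h, 66, 11 and 6 for sucrose against glucose, 7, 2 and 12 for fructose against sucrose, and 192 for strain by feeding. Of its 11 for sucrose against glucose at 6 h, 0 were called by edgeR. Without the filter on low counts, edgeR called 63 and 7 genes with glucose at 6 and 12 h, 119 with sucrose at 6 h, 259 and 28 for fructose against glucose at 3 and 6 h and 15 for sucrose against glucose at 3 h. In that setting the adjustment covers more genes, and beyond this the cause was not tested.

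With the suffix as a covariate, the counts were 254 and 20 with glucose at 6 and 12 h, 373 with sucrose and 312 with fructose at 6 h, 134 and 1 for fructose against glucose at 6 and 12 h, 11 for sucrose against glucose at 6 h and 190 for strain by feeding. The cause was not tested. In the libraries without the suffix, which are fewer, they were 1, 18 and 0 with glucose, 107, 50 and 0 with sucrose, 399, 16 and 0 with fructose, 99 and 3 for fructose against glucose at 3 and 6 h, and 7, 0 and 0 for sucrose against glucose. Strain by feeding gave 11, and strain by drink 3 and 2 at 3 and 6 h.

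Models of the libraries of the contrast alone estimate the spread from fewer libraries. They called 1471 genes at 12 h on water, 67 and 3 with glucose at 6 and 12 h, 494 and 3 with sucrose, 514 and 0 with fructose, 0 for fructose against glucose at 6 h and 13, 0 and 0 for sucrose against glucose. They called 817 between the strains, 3 for strain by feeding, and 0 and 0 for strain by drink at 3 and 6 h. Without the 5 libraries nearer to another feeding time, edgeR called 253 with glucose and 316 with sucrose at 6 h, 2 with fructose at 12 h, 20 for fructose against glucose at 6 h, 62 for sucrose against glucose at 3 h and 1 for fructose against sucrose at 3 h. The cause was not tested.

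Leaving out 1 replicate number, or BALB/c water 0 h replicate 1, leaves fewer libraries. The counts then ranged from 3243 to 4364, 3525 to 4937 and 1918 to 2962 for feeding, 2 to 39, 24 to 213 and 0 to 28 with glucose, 160 to 551, 35 to 296 and 0 to 5 with sucrose, and 640 to 1237, 59 to 238 and 0 to 3 with fructose. They were 102 to 463, 1 to 57 and 0 to 6 for fructose against glucose, 0 to 48, 0 to 7 and 0 to 1 for sucrose against glucose, and 0 to 1, 0 to 0 and 0 to 0 for fructose against sucrose. Between the strains they were 1805 to 2454, for strain by feeding 7 to 98, and for strain by drink 1 to 9, 8 to 33 and 0 to 1.

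The labels do not say that libraries with the same replicate number belong together. Of the pairs of libraries with the same number, 44.3%, 56.3%, 36%, 57.2% and 34.5% had correlations of residuals over 0.1 for replicates 1 to 5. Not every library correlated best with its own number, which held for 24 of 26, 20 of 26, 18 of 26, 19 of 24 and 6 of 26, a hint from the data and not the design. With the replicate block, the counts were 279 and 17 with glucose at 6 and 12 h, 333 with sucrose at 6 h, 1 for sucrose against glucose at 6 h and 5 for strain by drink at 3 h, and all other counts stayed within 1.5 times. The block kept 1021 of 1053 values of named genes and 159 of 162 list calls.

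Some results changed direction. Without replicate 3, Klk1 was at 0.55 for fructose against glucose and 0.32 for sucrose against glucose at 6 h, and Acsm2 at 0.18 for fructose against glucose at 6 h, since this leaves out the library with kidney transcripts. Over the fits without 1 library or replicate these values ranged from -5.81 to 0.55, -6.28 to 0.32 and -4.01 to 0.18. Nr4a1 at 12 h on water was at 0.17 without BALB/c water 0 h replicate 1, the highest of a range from -1.68. Sdf2l1 between the strains was at 0.14 without replicate 2 (range -1.68 to 0.14), 0.028 in the libraries without the name suffix and 0.094 without the 5 libraries nearer to another time. The immediate early list with glucose at 3 h had a camera adjusted p of 0.389 in the other direction without replicate 1, in a range from 0.000743. The correlation across genes of the fructose effects at 12 h in the strains was -0.05 over all genes and 0.222 over genes with a mean CPM of at least 5. For Nr4a1, Sdf2l1 and this correlation the cause was not tested.

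Of 162 list calls by camera, 16 held with an estimated correlation and 47 with fry, which does not compare a list with other genes. The suffix as a covariate kept 150, the model without the 5 libraries 154, and leaving out replicates 1 to 5 kept 119, 134, 140, 141 and 140. Total counts per library limit genes of low expression. In simulated libraries of this depth and group size edgeR recovered 54% of genes changed 1.5-fold and 84% of those changed 2-fold between fructose and water at 3 h, so smaller changes in the contrasts between drinks were often not detectable here.

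Each count was set against other splits of the same libraries into groups of the same sizes, 100 splits with the real one included, in a fit on the libraries of the contrast alone, from which the real value comes. For feeding the real split called 2926, 4004 and 1471 genes at 3, 6 and 12 h, the highest other split 8, 76 and 130, and 1 of 100 splits reached the real count at each time, so chance can be excluded. The same holds, with 1 of 100 splits each, for glucose at 3 h (24 genes, highest other 0) and 6 h (67, 1). It holds for sucrose at 6 h (494, 2) and fructose at 6 h (514, 2). At 3 h it holds for fructose (303, 1) and sucrose (13, 0) against glucose, and at 0 h for the strains (817, 294). For strain by feeding (3, 2) the counts are too close to exclude chance.

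With 2 of 100 splits chance is not excluded at 12 h for glucose (3 genes, highest other 1143). Nor is it at 3 h for sucrose (643, 2857) and fructose (1030, 1581). Where the real split called 0 genes, all 100 splits reach it whatever the data, so the comparison decides nothing about chance, and the genes that the model of all libraries called there have no such test. These were fructose at 12 h (highest other 3040), fructose against glucose at 6 h (2) and 12 h (799), sucrose against glucose at 6 h (1) and 12 h (1), fructose against sucrose at 3 h (15), 6 h (397) and 12 h (1396), and strain by drink at 3 h (2004), 6 h (755) and 12 h (2). A split that calls several times the real count points to a structure of the samples other than the groups, as for glucose at 12 h, sucrose at 3 h and the larger counts among those contrasts with 0. What those splits follow was not tested.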

Other observations

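The sums of transcripts of other tissues, the Xist level and the libraries named below were chosen after the data were examined, and the tests of genes and lists were fixed before. Txnip, which falls on water after feeding, was higher at 3 h with sucrose (log2 fold change 1.38 ± 0.28, SE, edgeR adjusted p = 0.000671, higher in 10 of 10 libraries) and with fructose (1.04 ± 0.27, 0.0081, 8 of 10, lost without replicate 2, 3 or 5) than with water. In BALB/c it was 96.9 ± 22.7 CPM (SD, n = 5) with sucrose and 35.9 ± 4.23 CPM with water. Pklr, the liver pyruvate kinase, rose with sucrose at 3 h (1.58 ± 0.38, edgeR adjusted p = 0.00647, 10 of 10, lost without replicate 3) and with fructose (1.14 ± 0.37, 0.0457, 9 of 10, lost without replicate 1, 3, 4 or 5).

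At 12 h genes of the unfolded protein response were higher with glucose than with water as a list (median log2 fold change 0.40, 12 of 20 genes higher adjusted over the list alone, none over all genes), with camera adjusted p = 1.01e-15 and adjusted p = 0.0726 with an estimated correlation. Manf was at 0.71 ± 0.23 (edgeR adjusted p = 0.3, higher in 8 of 9 libraries). Genes of fatty acid oxidation and ketogenesis were lower with sucrose at 6 h in 3 of 26 cases (4 adjusted over the list alone, median -0.26, camera adjusted p = 6.06e-07, adjusted p = 0.401 with an estimated correlation). At 12 h the same list was higher with fructose than with water (median 0.17, camera adjusted p = 3.47e-07, adjusted p = 0.36 with an estimated correlation), with none of its genes called.

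Transcripts of kidney, adrenal gland and stomach stood out in single libraries at 3 and 6 h, and those of muscle in many libraries up to 6 h. Summed kidney transcripts were 1768 CPM in BALB/c glucose 6 h replicate 3 and 1058 CPM in BALB/c water 6 h replicate 1, and the next highest library had 11.53 CPM. Summed adrenal transcripts were over 50 CPM in 4 libraries at 6 h, with 568.2 CPM in C57BL6/J water replicate 2, 306.5 CPM in BALB/c fructose replicate 2, 231.3 CPM in C57BL6/J glucose replicate 5 and 86.5 CPM in C57BL6/J sucrose replicate 1. Stomach transcripts were 120.7 CPM in C57BL6/J glucose 6 h replicate 2 and 95.27 CPM in BALB/c fructose 3 h replicate 2. Muscle transcripts were highest at 641.7 CPM in C57BL6/J sucrose 6 h replicate 1. Pancreatic acinar markers had a mean log2 CPM between -3.78 and 7.69, with a median of -2.14 and the highest value in C57BL6/J glucose 6 h replicate 3. Adipocyte markers were highest in BALB/c water 6 h replicate 1 at 3.98, where the median was 1.02.

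Xist, which is transcribed from the inactive X chromosome of females, was at 1146 CPM in BALB/c sucrose 3 h replicate 5 and at most at 3 CPM in the other libraries. The Y-linked genes Ddx3y and Eif2s3y stood at 74.5 and 64.4 CPM in that library, within the range of 39.4 to 150.3 and 36.8 to 119.8 CPM of all libraries. Material of 2 mice in this library is not excluded and was not tested. The library was kept in its group, and the strain by drink call of Xist at 3 h was lost without replicate 5.

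BALB/c water 12 h replicate 1 correlated at 0.493 with its own time and at 0.57 with 0 h, and BALB/c fructose 6 h replicate 3 at 0.421 with its own time and 0.442 with 3 h. In the former Igfbp1 was at 1939 CPM, Rgs16 at 486 CPM, Txnip at 477 CPM and Nr1d1 at 77.8 CPM. Its clock genes lay at 0.425 on the scale from 0 h to 12 h and its metabolic genes at 0.054, where the other BALB/c libraries at 12 h lay at 0.879 to 1.197 and 0.781 to 1.393.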
